A study of Rattus norvegicus with 14 samples.

How the data were processed

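Total RNA was taken from the supraoptic nucleus (SON), a hypothalamic nucleus of magnocellular neurons that make vasopressin and oxytocin, of male Sprague Dawley rats of 250 to 300 g. Per the labels' protocols, an adeno-associated virus carrying either a control microRNA (miCtl) or a microRNA against Rasd1 (miRasd1) had been injected into the nucleus, which was later cut out of 100 µm frozen sections with a 1 mm punch. The RNA of individual nuclei went into poly(A) libraries, per the same protocols. The series holds 14 libraries, 7 miCtl and 7 miRasd1, and the titles number them 1, 2, 3, 4, 8, 11 and 12 in both groups. The labels do not say whether libraries came from separate rats, nor whether a shared number marks the left and right nucleus of a rat, so p-values measure the spread between these punches.

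The submitters' processing notes name FastQC, STAR, featureCounts and DESeq2. Their versions, the genome build and the strand setting of the counting are not given in the sources used here. The authors deposited a table of 32623 genes under Ensembl rat gene IDs, with a signal value per library that is a read count divided by a single size factor for that library (a normalised read count). The same deposited table holds the authors' log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value per gene. Dividing each library's values by the smallest step between them gave whole reads for 100% of non-zero values, within a tolerance of 0.001. The recovered reads numbered 19968058 to 28345441 per library. The smallest chi-square per degree of freedom between any pair of libraries was 4.98 over 91 pairs, above the 1 of sampling noise, so no library was treated as a copy of another. This does not show that libraries are separate biological replicates. DESeq2 1.42.0 was run on the recovered reads and compared over the 18337 genes with a mean above 1 normalised read and a p in every fit. Without a block its p was within 0.001 of the authors' p for 100% of them, against 2.20% with the replicate number as a block.

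The deposited table does not pair its IDs with gene symbols, and the table of 47357 rat genes (GRCr8 assembly) used here holds 0 Ensembl IDs, so none of the 32623 could be looked up. Rasd1, Avp, Oxt and the 44 gene lists (functions, cell types of the punch and RNA quality) fixed before the data were examined were therefore not tested, and the level of the knockdown target was not checked. The rule for naming genes took the largest rises and falls with an adjusted p under 0.05, a mean of at least 1 CPM (reads scaled to an equal library total) and at least 6 of the 7 miRasd1 libraries on the called side of the miCtl mean, and passed over IDs without a symbol. With no symbols, the last condition was dropped and the rule was limited to 2 IDs that rose and 2 that fell. Only 1 gene fell in the unblocked test, so the other fallen ID came from the test with a replicate block and was chosen after its values were seen.

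The planned count test was replaced by limma (3.58.1), as foreseen for normalised values. The limma-trend test, with Benjamini-Hochberg adjustment and a threshold of 0.05, ran on log2(value + 1) of the 15178 genes with a value of at least 10 in at least 7 libraries. Log2 fold changes are on this scale, where the added 1 understates the change of low genes. For each named gene they were still somewhat larger in size than the authors' values, for example 1.86 against 1.68 for ENSRNOG00000057315. Whether the numbers pair the libraries was decided from the correlation, over genes, of deviations from the group mean. Libraries with the same number correlated at 0.20 to 0.40 (median 0.30), every one above the bound of 0.1, and libraries with different numbers at −0.23 to 0.14 (median −0.05). Each of the 7 miCtl libraries correlated best with the miRasd1 library of its own number. The pairing thus comes from the values and from the numbers in the titles, and limma with the number as a block is given beside the unblocked test.

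On counts simulated from the 14 libraries for the same 15178 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold, unblocked limma recovered 74% and 88% with 0 false calls among 162. With the block it recovered 86% and 91%, with 18 false calls among 195, which is above the nominal 5%. edgeR recovered 73% and 88% (0 false calls among 161) and DESeq2 81% and 89% (2 false calls among 172). The simulation was a single draw with noise independent between genes, whereas the genes called here varied together. Its false calls therefore may not carry over to the real data. The simulated counts kept the fitted differences between replicate numbers. These widen the noise of the unblocked fits without entering the group difference, so the few false calls of those fits are partly built in.

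Single values were compared with exact two-sided permutation tests of 7 against 7 libraries, whose smallest possible p is 0.000583, and with exact two-sided sign-flip permutation tests over the 7 pairs, whose smallest possible p is 0.0156. Alternatives set beforehand were pseudocounts of 0.5 and 5, no filter, edgeR 4.0.16 (several normalisations and filters), DESeq2 and limma-voom on recovered reads, the block, and leaving out each library or pair. Other scalings in limma, thinning to equal depth and the blocked versions of the remaining settings were added after the data were seen. Held-out lists, genes ordered alike in every pair, covariation within the called genes and swaps within pairs were also added once the values had been looked at. Covariation was set against 1000 random lists of the same size, drawn within 200 ranks of mean abundance. Computations ran in R 4.3.3.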

Results

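Gene expression was profiled by RNA sequencing in punches of the rat SON after viral delivery of a microRNA against Rasd1, which encodes a small G protein of the Ras family, or of a control microRNA, in rats with normal water balance. Of the 14 libraries, 7 were miCtl and 7 miRasd1. Depth was 21654150 ± 1524820 reads in miCtl and 22650159 ± 2774107 reads in miRasd1 (SD, n = 7 each; exact permutation p = 0.478), and ranged from 19968058 to 28345441 reads. The number of genes with at least 1 read was 19061 ± 148 in miCtl and 19118 ± 168 in miRasd1 (exact permutation p = 0.514, n = 7 each). The 10 most abundant genes held 7.77 ± 0.49% of normalised counts in miCtl and 7.54 ± 0.43% in miRasd1 (exact permutation p = 0.354, n = 7 each). No gene carries a symbol here, so Rasd1 itself, the hormone genes and cell type markers are not reported.

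Libraries with the same number deviated from their group means together. The correlation across genes, which are not independent replicates, was 0.20 to 0.40 for the 7 same-number pairs, and its median was −0.05 between different numbers.

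**Figure D1:**
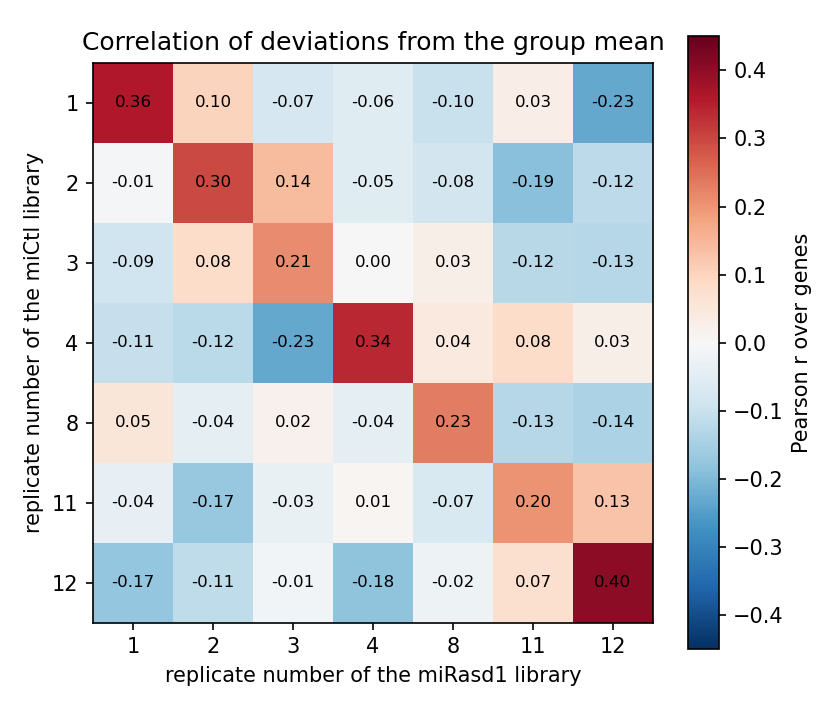
Pearson correlation, over 15178 genes, of the deviations from the group mean on the log2 scale, for each miCtl library (vertical axis, replicate number) against each miRasd1 library (horizontal axis, replicate number). The diagonal, where numbers match, holds the highest value of each line (0.20 to 0.40).

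The first principal component of the tested genes held 17.5% of the variance, and its sign was set so that miRasd1 is the higher group. It averaged −7.16 ± 11.2 in miCtl and 7.16 ± 9.42 in miRasd1 (SD, n = 7 each; exact permutation p = 0.0268, n = 7 each). The miRasd1 library lay higher in 7 of 7 pairs (exact sign-flip permutation p = 0.0156, the smallest this test can give). Over the 4 library measures compared between groups, the Benjamini-Hochberg adjusted values were 0.107 (exact permutation) and 0.0625 (exact sign-flip permutation), so the difference did not pass the threshold once adjusted.

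The comparison of miRasd1 with miCtl asked which transcripts of the SON change when Rasd1 is knocked down. In unblocked limma, 21 genes rose and 1 fell at a Benjamini-Hochberg adjusted p under 0.05, 22 of 15178 tested. The 21 that rose had a median log2 fold change of 0.81 (0.38 to 1.86), and 8 of them at least doubled. All 22 moved in their called direction in 7 of 7 pairs, though they were selected on the difference between these same libraries. With the replicate number as a block, limma called 150 genes, 119 higher and 31 lower, and these included all 22 of the unblocked test. Without the filter on low values, limma with the block called 0 genes (2641 of 23233 at an unadjusted p under 0.05), and DESeq2 with the block called 314. The 119 had a median log2 fold change of 0.46 (0.16 to 1.98), with 17 at least doubled, and the 31 had a median of −0.23 (−0.84 to −0.13), with 0 lowered by a log2 change of 1 or more. Of these genes, 101 higher and 24 lower moved the same way in all 7 pairs, on which they had also been selected. Scaling by total reads gave 132 higher and 18 lower with the block (88.0% higher, against 79.3%). In a single simulated draw, with noise independent between genes, the blocked test made 18 false calls among 195, above the 5% that the threshold allows.

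At an unadjusted p under 0.05, limma found 1499 genes without the block (848 higher, 651 lower) and 2264 with it (1231 higher, 1033 lower). The mean expected by chance is 758.9. Genes vary together, so a chance count can lie far from this mean, and these counts were not set against swapped labels. The median log2 fold change of all tested genes was −0.0012. The number of calls depended on single libraries. Unblocked limma called 1 gene without miCtl 4, miCtl 11, miRasd1 1, miRasd1 3 or miRasd1 12, 2 without miCtl 12 or miRasd1 4, and 7 without miCtl 3, but 59 without miRasd1 11 and 81 without miRasd1 8. With the block, it called 0 genes without pair 1, pair 4 or pair 12 (2063, 1843 and 1808 at an unadjusted p under 0.05), 38 without pair 3, 78 without pair 11 and 484 without pair 8. The median log2 fold change of the 119 genes, which had been called with all pairs included, was 0.45, 0.46 and 0.44 without pairs 1, 4 and 12, with a median SE of 0.10 each, against 0.46 and 0.09 in full.

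**Figure D2:**
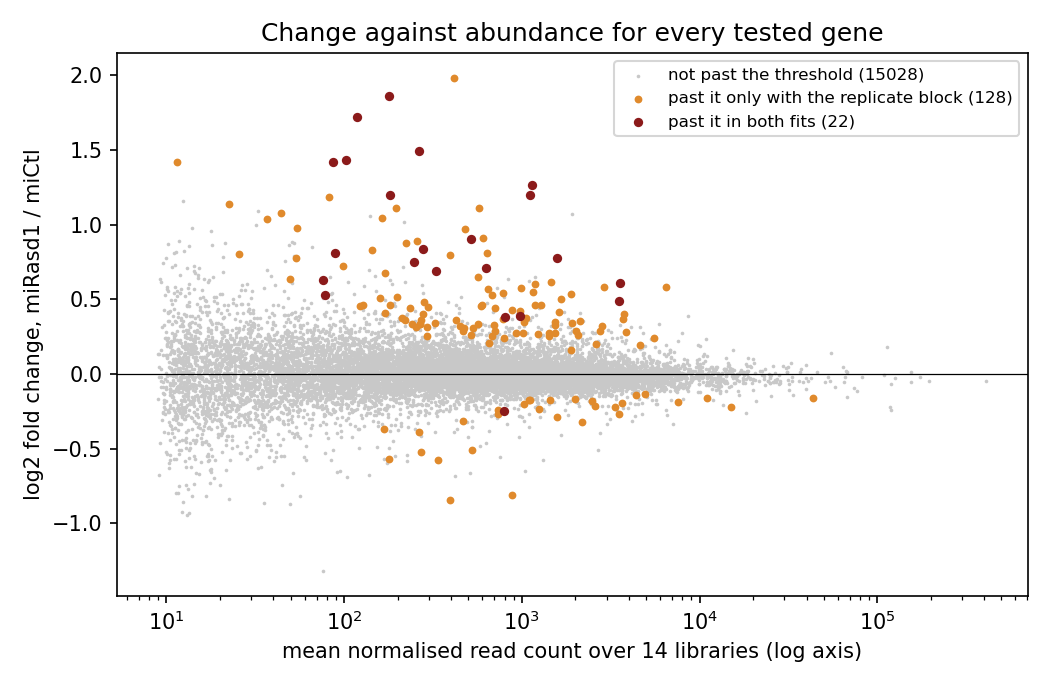
Log2 fold change of miRasd1 over miCtl (vertical axis) against the mean normalised read count over 14 libraries (horizontal log axis) for the 15178 tested genes, 1 point per gene. Dark red points are the 22 genes past the adjusted p threshold with and without the replicate block, orange points the 128 past it only with the block, and points above 0 outnumber those below 0 among both.

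The named genes were picked from the calls on these libraries, so their exact permutation tests are no separate support. Among the genes that rose, ENSRNOG00000057315 had the largest log2 fold change of the unblocked calls, 1.86 (SE 0.36, limma adjusted p = 0.0495, 0.0358 with the block). Its level was 85.4 ± 54.8 normalised reads in miCtl and 274 ± 102 in miRasd1 (SD, n = 7 each; exact permutation p = 0.000583), and it was higher in 7 of 7 pairs. ENSRNOG00000013869 went from 57.4 ± 23.9 to 179 ± 30.0 normalised reads (SD, n = 7 each), a log2 fold change of 1.72 (SE 0.22, limma adjusted p = 0.00642, 0.0161 with the block; exact permutation p = 0.000583). The highest miCtl library of ENSRNOG00000013869 held 87.2 normalised reads and the lowest miRasd1 library 147. The gene that fell, ENSRNOG00000051960, changed little in size, from 862 ± 39.5 to 726 ± 46.2 normalised reads (SD, n = 7 each), a log2 fold change of −0.25 (SE 0.05, limma adjusted p = 0.0473, 0.0275 with the block; exact permutation p = 0.000583). ENSRNOG00000057703, chosen after its values were seen, measured 507 ± 132 normalised reads in miCtl and 286 ± 91.0 in miRasd1 (SD, n = 7 each). Its log2 fold change was −0.84 (SE 0.19, limma adjusted p = 0.0882 without and 0.0465 with the block, exact permutation p = 0.00291), and it was lower in 6 of 7 pairs. Over the 7 pairs, the exact sign-flip permutation p was 0.0313 for ENSRNOG00000057703. For each of the other named genes it was 0.0156, the smallest this test can give.

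Across 37 alternative settings the adjusted p of ENSRNOG00000013869 was 1.97e-11 to 0.0785 and passed the threshold in 36, failing without pair 4. ENSRNOG00000057315 passed in 14 of them (0.00725 to 0.249), ENSRNOG00000051960 in 15 (0.00054 to 0.258) and ENSRNOG00000057703 in 4 (0.0302 to 0.414), and the direction of each stayed the same in all 37. Log2 fold changes over these settings were 1.54 to 1.88 for ENSRNOG00000013869, 1.51 to 2.14 for ENSRNOG00000057315, −0.27 to −0.22 for ENSRNOG00000051960 and −1.01 to −0.70 for ENSRNOG00000057703.

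**Figure D3:**
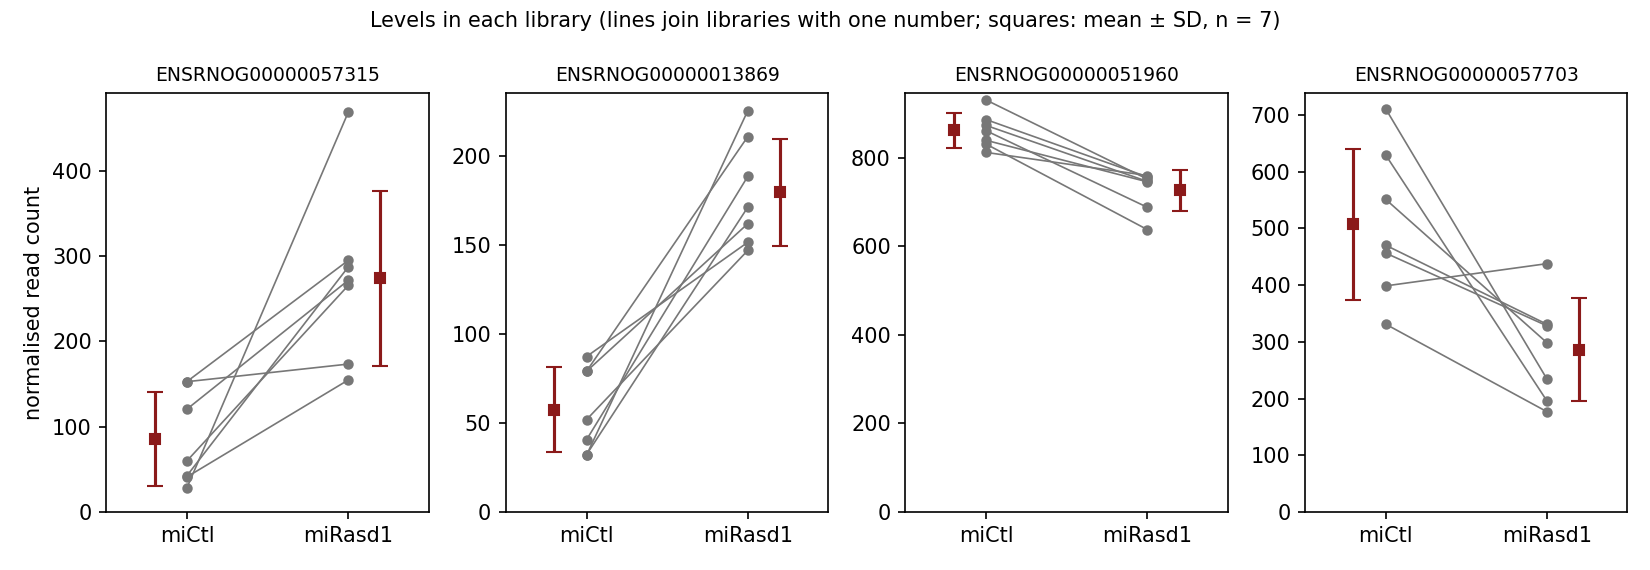
Normalised read count (vertical axis, starting at 0) of 4 genes in each miCtl and miRasd1 library; grey lines join libraries with the same number, and red squares with bars are the mean and SD (n = 7). ENSRNOG00000013869 does not overlap between groups (at most 87.2 in miCtl, at least 147 in miRasd1), whereas ENSRNOG00000057703 rises in 1 of 7 pairs.

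The authors' deposited table lists 172 genes with an adjusted p under 0.05, 133 higher and 39 lower in miRasd1, among 15296 with an adjusted p. Log2 fold changes of these 172 in the authors' deposited table run from −0.83 to 2.00. Of the 172, 169 were tested here; all 22 unblocked limma calls and 101 of the 150 blocked calls are among the 172 of the authors' deposited table.

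Every miRasd1 library lay above every miCtl library in 35 genes, and below in 18. Chance gives such a separation in 0.0583% of genes, or 8.84 of those tested, if all libraries are exchangeable. Under swaps of labels within pairs, 1 of 64, the real one, separated as many as 53 genes, with a median of 2 and a highest value of 29 among the others. The separated genes included 17 of the 22 unblocked calls and 32 of the 150 blocked calls. In 370 genes the miRasd1 library was higher in all 7 pairs, and in 316 it was lower, 686 in total against 237 by chance (1.56% of genes). Among the 64 ways of swapping labels within pairs, the median of the other swaps was 203 genes, but the highest was 872.

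To see whether a change found in some pairs held in another, the 100 genes with the highest and the 100 with the lowest blocked limma statistic in 6 pairs were read in the pair left out. The median log2 difference of the highest 100 was 0.51 in pair 1, 0.13 in pair 2, 0.99 in pair 3, 0.48 in pair 4, 0.04 in pair 8, 0.29 in pair 11 and 0.44 in pair 12. It was above 0 in 7 of 7 left-out pairs (exact sign-flip permutation p = 0.0156, 0.0313 adjusted over the 2 lists). The lowest 100 had a median of −0.13 over the left-out pairs and were below 0 in 6 of 7 (exact sign-flip permutation p = 0.0469, adjusted 0.0469), with 0.08 in pair 8. Left-out pairs share the other pairs among their lists, so these 7 values are not fully independent.

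**Figure D4:**
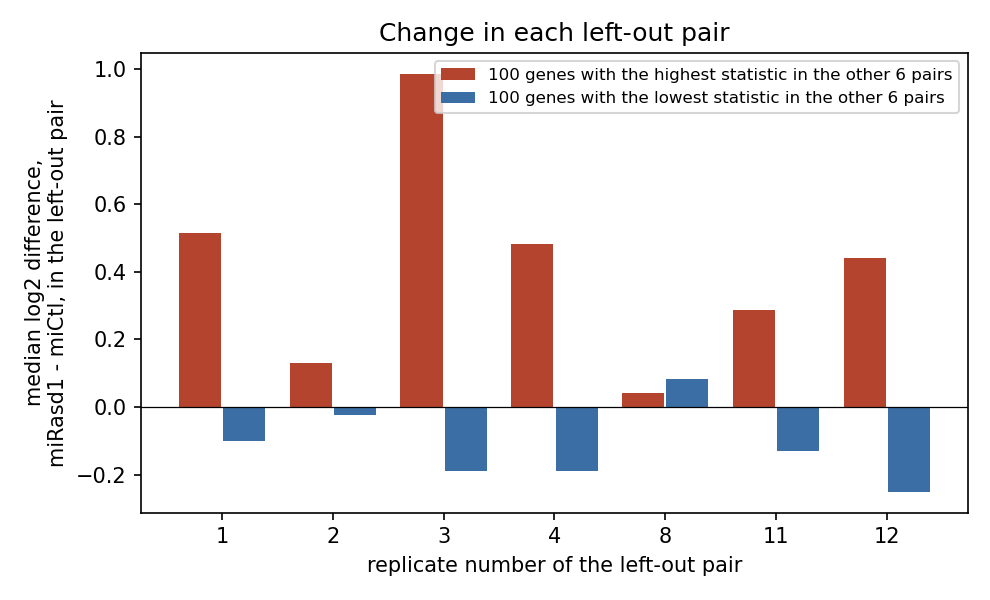
Median log2 difference between the miRasd1 and miCtl libraries of each pair (vertical axis, bars from 0; horizontal axis, replicate number) for genes chosen without that pair: the 100 with the highest (red) and the 100 with the lowest (blue) blocked limma statistic in the other 6 pairs. Red bars run from 0.04 in pair 8 to 0.99 in pair 3, and blue bars lie below 0 except in pair 8 (0.08).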

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

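In the knockdown group, library miRasd1 11 stood apart in depth, with 28345441 reads against 19968058 to 23436467 in the other 6. Its gap to the nearest library was 0.586 of the group's range, beyond the limit for 7 samples at 95% confidence. Across the 20 sets of 7 values tested in this way it was the only such case, and chance gives about 1 in 20. Without this library unblocked limma called 59 genes in place of 22.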

How the results depend on the processing

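Scalings in limma, thinning to equal depth and all blocked settings other than plain limma and edgeR with the block were chosen after the data were seen. Unblocked limma called 22 genes (21 higher, 1 lower). The replicate block, which the pairing of the numbers calls for, gave 150 (119 higher, 31 lower) in limma and 139 (113 and 26) in edgeR. Without a block, DESeq2 on recovered reads gave 172 (133 and 39), edgeR with no filter 57 (51 and 6) and limma-voom 8 (8 and 0). The lower count was 0 with edgeR on DESeq2 size factors, limma on TMM scaling and limma on thinned reads. Beside the blocked count of 150, DESeq2 gave 314 (238 and 76), limma on total reads 18 lower genes, and limma with no filter 0, 0 higher and 0 lower (smallest adjusted p 0.0553, 2641 of 23233 genes at an unadjusted p under 0.05). The cause of these differences was not tested.

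Leaving out a library or a pair moved the unblocked total over 0 to 81 (0 to 57 higher, 0 to 24 lower), with 0 without pair 4 (1147 at an unadjusted p under 0.05), 1 without pair 12, 2 without pair 1 or 3 and 39 without pair 8. Leaving out a pair moved the blocked total over 0 to 484 (0 to 309 higher, 0 to 175 lower). The smallest adjusted p was 0.0547, 0.111 and 0.0519 without pairs 1, 4 and 12, where the count was 0. The group difference of the first principal component was 10.7 to 17.3 when a library or pair was left out, and its exact permutation p rose above 0.05 without miCtl 4 (0.0798), miRasd1 1 (0.119), miRasd1 3 (0.112), pair 1 (0.0606), pair 3 (0.143) and pair 4 (0.108). Among the 4 named genes, the block moved the call of ENSRNOG00000057703 alone in limma, and of ENSRNOG00000057315 alone in edgeR (adjusted p 0.0639 without, 0.0390 with it). Fits with an oligodendrocyte covariate and tests of Rasd1, Avp, Oxt and gene lists were not run, for want of gene symbols. In the lowest of 5 equal classes of abundance, counting noise calculated from the mean reads had a median SD of 0.25 (log2), against a residual SD of 0.30 in the blocked fit. In the highest class these were 0.03 and 0.07.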

Other observations

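The tests in this part, other than the splits of the 14 libraries, were chosen after the data were seen. Those of equal depth, of a single outlying pair and of swaps in the fit with the block were set before their own outcome was known, and the rest after it or a closely related value had been seen.

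Large falls were not seen among abundant transcripts. Of the 12038 tested genes with a mean of at least 100 normalised reads, 0 were lower by a log2 change of 1 or more, and the lowest value was −0.84, whereas 14 were higher by at least 1. Above a mean of 10 normalised reads, 1 of 15133 genes was lower by that much (−1.32), but its limma adjusted p was 0.676 (0.483 with the block), and its miCtl level of 137 ± 328 normalised reads (SD, n = 7) came mostly from a library at 880. When a pair was left out, the count of 14 higher by at least 1 ran from 6 (without pair 3) to 18 (without pair 8). For the falls, 1 of the 12038, ENSRNOG00000057703, had a log2 fold change of −1.01 without pair 8, and without any other pair the count stayed at 0. Which of these genes, if any, is the target of the microRNA was not tested.

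Counts of rises and falls by abundance were as follows. With the block, limma called 15 higher and 0 lower genes in the lowest of 5 equal classes of abundance, 34 and 5, 25 and 5, and 27 and 8 in the next ones, and 18 and 13 in the highest. The difference between classes was not tested.

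More genes rose than fell among the calls. At an unadjusted p under 0.05 with the block the excess was smaller (1231 higher, 1033 lower), and it was not tested against swapped labels. The choice among 4 scalings (size factors, TMM, upper quartile, total reads) is argued against as the source, since limma with the block called at least 75.8% of its genes higher under each of them (116 higher and 37 lower at the least, 132 and 18 at the most). Unequal depth is argued against as well: after thinning to the shallowest library, limma with the block still called 114 higher and 26 lower genes. The knockdown itself, the biological explanation in the design, stays open as a hypothesis, as does a difference between punches or in the response to the injected virus, which the groups do not separate.

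The called genes moved as sets. Over the 7 pairs the differences of the 119 risen genes had a mean pairwise correlation of 0.44. For random lists of like abundance, 95% gave −0.006 to 0.015. The correlation stayed at 0.336 or more whichever pair was left out, which argues against a single outlying pair as its only source. The random lists were not chosen on a group difference, so part of the covariation may come from the selection. Nor were the 119 genes chosen anew when a pair was left out. These genes also varied together among the 7 miCtl libraries, at 0.424, so a component of the tissue that differs between punches with or without the knockdown may carry them, and 119 calls may then stand for few independent changes. Their mean log2 level, centred over all libraries, was −0.30 ± 0.19 in miCtl and 0.30 ± 0.21 in miRasd1 (SD, n = 7 each) without overlap, though the genes were selected on this difference. The 31 fallen genes covaried as well, at 0.27 over the pairs and 0.37 among the miCtl libraries, where the upper bound for 95% of random lists was 0.07 and 0.06, and which cell type or state such a component would be was not tested.

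Single pairs set the number of calls. That pair 1 carried the change is argued against, since 100 genes chosen in 5 pairs, without pair 1 and without the pair read, had a median log2 difference above 0 in 6 of 6 pairs (0.0007 in pair 8 to 0.85 in pair 3, median 0.33; exact sign-flip permutation p = 0.0313, the smallest this test can give), although the count of calls went from 150 to 0 without pair 1 (smallest adjusted p 0.0547; median log2 fold change of the 119 genes called with all pairs 0.45, SE 0.10, against 0.46 and 0.09). The 6 lists share pairs, so their values are not fully independent and the sign-flip p is only approximate. The value in pair 8 was hardly above 0. No other pair was put to this test, although the blocked count was also 0 without pair 4 or pair 12. Pair 8 may have responded less than the others: the 100 genes with the highest statistic elsewhere had a median log2 difference of 0.0426 there. Library miRasd1 8 also differed from most other libraries. Its chi-square per degree of freedom was 13.2 to 23.3 against every library but miCtl 8 (8.19), where the median of all library pairs was 12.3. The highest value of any pair, 27.9, was between miCtl 4 and miRasd1 3. Whether an atypical library or a weaker response lies behind pair 8 was not tested. Exchanged labels in pair 8 stay open, since the evidence goes both ways: of the 33 genes called higher in unblocked limma without this pair, 28 were higher in pair 8 (median 0.315, against 0.76 in the other pairs), whereas 5 of the 6 called lower were higher there too. With the block, 174 of the 309 genes called higher without pair 8 were higher in pair 8 (median 0.02, against 0.37 in the other pairs). So were 117 of the 175 called lower (median 0.06, against −0.28 in the other pairs). Both medians in pair 8 were small, whereas a full exchange would reverse the change at a similar size. The genes were chosen in the other pairs, however, which enlarges their medians there.

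Chance is argued against for the unblocked count, though not excluded. Of 100 splits of the 14 libraries, 1, the real one, gave as many genes (22), and the highest of the others gave 2. Only 3 of the 99 other splits part all 7 pairs as the real one does, so the labels were also swapped within pairs, a test added later: 1 of 64 swaps, the real one, gave as many genes in unblocked limma, and the highest of the others gave 0. For the blocked count, 2 of 64 swaps within pairs gave as many genes, which is under the 5% bound and argues against chance without excluding it. However, the highest other swap, in which only pair 8 was reversed, gave 186 genes against the real 150, so the stated grouping was not the one with the most calls, and the structure of pair 8 weighs on the blocked count.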
